A study of Mus musculus with 12 samples.

How the data were processed

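Whole-heart total RNA of 12 male mice aged 4 months was sequenced, 6 hearts of each genotype. Groups were taken from the genotype in the labels, and each library is a separate mouse according to the series design text. The deposited table holds raw counts of reads per gene for 24061 gene identifiers, which the authors made before deposit. Per the submitters' processing notes, bcl2fastq, CASAVA 1.8, TopHat and DESeq were named along with the mm10 build, and per the design text the platform was a HiSeq 1000. The counting program, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Gene names and coordinates came from the RefSeq annotation of GRCm38.p6, the same build, and exon positions from GENCODE M21. Of the identifiers, 23976 matched a name and 85 did not.

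Some near-identical genes hold the same count in every library, such as Hba-a1 and Hba-a2, or Tmem254b and Tmem254c. Of 13883 genes with more than 120 reads in all, 97 share all their counts with another gene. Among the tested genes, whatever their reads, 93 do so. Values for such copies are uncertain and are not independent of each other. Over the 66 pairs of libraries, a chi-square per degree of freedom on counts ran from 6.66 to 44.7, so no library repeated another.

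The counts were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and knockout was compared with wild type by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05 over 13832 genes. Standard errors were derived from the F statistic, and intervals are at 95%. Single values were compared by exact permutation tests over all regroupings of the 12 hearts. Gene lists were tested against other genes with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Of 30 lists fixed beforehand, 27 had at least 3 tested members and a test. The sex genes were used for values only, and Eif2s3y on the Y chromosome averaged 90.8 and 101.7 CPM in the 2 groups.

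The genes named were fixed by a rule. It takes Slc4a4 first, then the 10 with the smallest adjusted p in each direction among genes past the threshold, or, where fewer than 5 pass, the 5 with the smallest unadjusted p, as values. It adds the 5 largest changes that passed, the called members of each list or otherwise the 2 with the smallest p, and fixed transporters and cardiac genes. Predicted and unnamed genes are skipped. Some genes that the rule takes are not reported here. The groups, tests, gene lists and alternatives were chosen before the data were examined. Because no gene was called, the planned test for clustering of called genes along chromosomes could only give 0 chromosomes. With the 3 genes at an adjusted p under 0.1 it also gave 0. Genes that DESeq2 called outside the rule, the genes of chromosome 4 and the liver and blood transcripts were chosen after their values were seen.

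Alternatives were DESeq2 1.42.0, limma-voom with and without library weights, other scalings, other count filters, the 10 most abundant genes left out, 1 surrogate variable (sva 3.50.0), other thresholds, and each library left out in turn. The edgeR exact test, other quasi-likelihood options, shared counts taken once and the removal of W2 and K7 together were added after seeing the data. The scripts were tested on simulated counts with 200 genes changed by known folds, 50 at each of 4 sizes and all with a mean of at least 5 CPM, among 13832 genes. edgeR recovered 34% at 1.25-fold, 72% at 1.5-fold, 96% at 2-fold and 100% at 3-fold, with 10 false calls, and DESeq2 recovered 46%, 82%, 96% and 100%, with 23 false calls. With fewer genes changed the adjustment is stricter, and the shares recovered there were not measured. A list shifted by 0.3 on the log2 scale was recovered, and 0 other lists were called. The simulated genes were drawn independently, so this does not show how camera behaves where list members are correlated. Plots were drawn with matplotlib 3.10.9.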

Results

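RNA from the entire heart was sequenced in male mice aged 4 months in which NBCe1, the electrogenic sodium-bicarbonate cotransporter encoded by Slc4a4, was deleted in cardiac myocytes, and from hearts of mice that carried the floxed alleles without Cre recombinase. Each group held 6 hearts, 1 library per mouse, here named W1 to W6 (wild type) and K7 to K12 (knockout). The libraries held 10631869 to 13327519 counts each, with 16248 to 16919 genes detected by at least 1 read. Wild-type libraries were deeper, at 12455870 ± 842736 counts (SD, n = 6) against 11274054 ± 773973 in knockout libraries (SD, n = 6; exact two-sided permutation p = 0.030). The comparison asks how loss of the cotransporter from cardiac myocytes changes the transcripts of the heart. Because only the knockout mice carried Cre, the deletion and the presence of Cre were not separated by the design.

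Slc4a4 itself averaged 87.2 ± 17.8 CPM (counts scaled to a library of 1000000) in wild-type hearts and 49.9 ± 11.7 CPM in knockout hearts (SD, n = 6 each). The log2 fold change was -0.81 with a standard error of 0.14, or 42.8% lower, with a 95% interval from -53.4% to -29.7%. On this gene alone few regroupings of the hearts gave as large a difference in means (exact two-sided permutation p = 0.00433, over 924 regroupings). Corrected for all genes tested it missed the threshold of 0.05, with an edgeR adjusted p of 0.089, whereas DESeq2 gave an adjusted p of 0.000605. In 5 of 6 knockout hearts the value lay below every wild-type heart, and K8, at 68.5 CPM, lay above the lowest wild-type heart, W5, at 63.6 CPM. Without K8 the edgeR adjusted p was 0.028. Slc4a4 lies on chromosome 5 from 88793858 to 89239656 (GRCm38), and the design deletes exon 12. Exon 12 spans 89135646 to 89135820 in 3 of the 4 annotated transcripts that have an exon 12, and whether the study numbered exons in the same way is not given in the sources used here. The counts cover the whole gene, so reads from exons that were not deleted and from cells other than myocytes remain in these values.

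**Figure D1:**
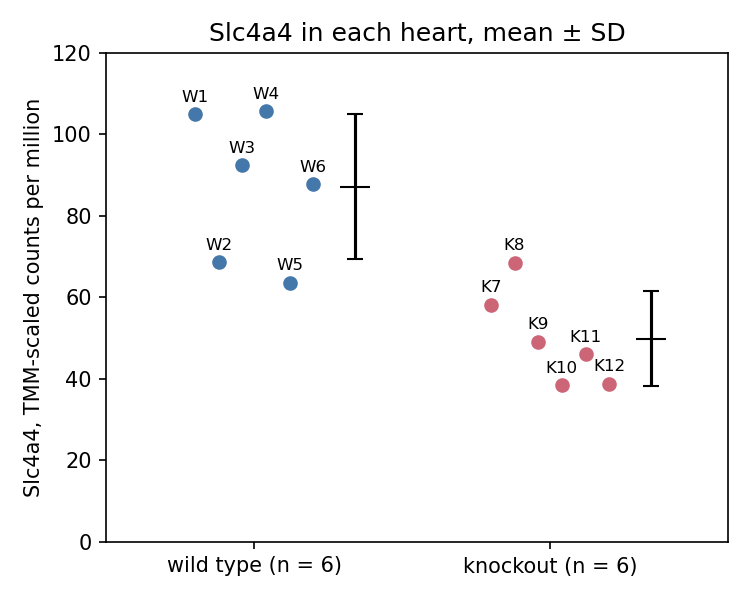
Slc4a4 in each of the 12 hearts, in TMM-scaled CPM (vertical axis), by genotype (horizontal axis). Points are single hearts and bars are the mean ± SD of 6 hearts; 5 of 6 knockout hearts lie below every wild-type heart, and K8 lies at 68.5.

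Across the 13832 genes tested, none passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 562 genes, 286 higher and 276 lower in knockout, where 691.6 would be expected by chance, and limma-voom also called 0 genes. DESeq2, run as an alternative, called 11 genes, 9 higher and 2 lower, and 5 of these were too low to enter the edgeR test. The 2 lower genes were Slc4a4 and Dmxl2. The 9 higher genes were Zfp985, Alb, Msrb3, Cacna1s, Tmem51os1, Mup13, Mup17, Cyp3a41a and Cyp3a41b. In the simulated counts DESeq2 made 23 false calls, against 10 by edgeR, so more of its calls may be false. In edgeR, 3 genes had an adjusted p under 0.1, namely Alb, Slc4a4 and Zfp985. The values of 35 genes did not overlap between the groups, 0.253% of those tested against 0.216% by chance.

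The genes with the smallest p in each direction are given as values. Zfp985, a zinc finger gene on chromosome 4, averaged 3.13 ± 0.79 CPM in wild type and 6.75 ± 1.40 CPM in knockout (SD, n = 6 each; log2 fold change 1.10, SE 0.20, edgeR adjusted p = 0.089). Cacna1s, which encodes the skeletal muscle L-type calcium channel subunit, averaged 27.6 ± 1.4 and 39.8 ± 7.7 CPM (log2 fold change 0.53, SE 0.11, edgeR adjusted p = 0.39). Of the 6 knockout hearts 5 lay above every wild-type heart, and K9, at 25.3 CPM, lay below every wild-type heart. Msrb3, a methionine sulfoxide reductase, averaged 240.4 and 285.2 CPM and was higher in 6 of 6 knockout hearts than in every wild-type heart (log2 fold change 0.25, edgeR adjusted p = 0.55). Adam11 averaged 11.5 and 16.6 CPM (edgeR adjusted p = 0.82). On the lower side, Dmxl2, a subunit of the complex that assembles the vacuolar proton pump, averaged 71.0 ± 3.2 and 55.9 ± 6.1 CPM (log2 fold change -0.35, SE 0.08, edgeR adjusted p = 0.42), and 6 of 6 knockout hearts lay below every wild-type heart. Epn3 averaged 24.6 and 16.6 CPM (edgeR adjusted p = 0.55) and Mtrf1l 14.3 and 10.2 CPM (edgeR adjusted p = 0.64). Plac9a averaged 9.54 ± 3.58 and 5.10 ± 0.80 CPM (edgeR adjusted p = 0.55), and it lies among near-identical copies on chromosome 14 whose reads the counting may have shared.

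Alb, the serum albumin gene and a liver transcript, had the smallest p. It averaged 0.358 ± 0.403 CPM in wild type and 15.4 ± 23.5 CPM in knockout (SD, n = 6 each; log2 fold change 5.43, SE 0.89, edgeR adjusted p = 0.083). K7 held 62.2 CPM (794 reads), K8 to K11 held 4.13 to 9.78 CPM, K12 held 1.34 CPM, and no wild-type heart held more than 1.13 CPM. Without K7 the log2 fold change of Alb was 4.02 and its edgeR adjusted p was 0.026. The Mup and Cyp3a41 transcripts called by DESeq2, also typical of liver, were highest in K7. Mup13 averaged 0.028 CPM in wild type and 1.28 CPM in knockout, and Cyp3a41a 0 and 1.51 CPM.

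Other genes of acid-base transport, which are transporters of bicarbonate, protons or lactate and carbonic anhydrases, did not pass the test. Of the 19 tested members of that list, 8 had positive and 11 negative fold changes, 0 passed over all genes and 0 adjusted over the list alone. Slc16a3, a lactate transporter, averaged 0.725 CPM in wild type and 1.39 CPM in knockout, and Slc9a9 averaged 3.39 and 4.87 CPM. The related bicarbonate transporters had log2 fold changes of -0.18 for Slc4a2, -0.11 for Slc4a3, 0.06 for Slc4a7 and -0.17 for Slc26a6, each with an interval that included 0. Slc4a5 was too low to be tested.

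Genes of contraction and calcium handling also gave no call. Of 26 sodium and calcium handling genes, 13 had positive and 13 negative fold changes. Casq2, the calcium-binding protein of the sarcoplasmic reticulum, averaged 1105 and 1216 CPM, Camk2b 14.5 and 11.7 CPM, and Slc8a1, the sodium-calcium exchanger, 800.8 and 871.3 CPM. Atp2a2, the calcium pump of the sarcoplasmic reticulum, averaged 15232 and 15165 CPM, with a log2 fold change of -0.01 whose sign changed when W1, W6 or K11 was left out. Myh6 averaged 17376 and 16152 CPM (log2 fold change -0.11), and Myh7 averaged 4755 and 4754 CPM, with a fold change near 0 whose sign changed under library totals and when single hearts were left out. The natriuretic peptide genes averaged 777.3 and 835.6 CPM for Nppa, and 90.0 and 105.4 CPM for Nppb, whose log2 fold change of 0.22 became -0.12 without K9. Of the 13 tested hypertrophy genes, 20 sarcomere genes and 25 extracellular matrix genes, 0 passed over all genes and 0 adjusted over the list alone. Col3a1 averaged 294.2 and 333.3 CPM and Fn1 57.0 and 49.0 CPM. Among 22 potassium channel and conduction genes, Kcnj2 averaged 129.5 and 152.5 CPM and Kcnj11 79.9 and 91.4 CPM. In the adrenergic list Adra1a, an alpha-1 adrenergic receptor, averaged 39.9 ± 6.6 and 30.6 ± 3.8 CPM. It was the 1 of 19 members that passed adjusted over the list alone, while over all genes 0 passed.

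Metabolic and stress lists gave no call. The median log2 fold change was -0.03 for 24 fatty acid oxidation genes, 0.02 for 23 glucose metabolism genes and -0.04 for 25 respiratory chain genes. It was -0.03 for 25 apoptosis genes, 0.02 for 23 heat shock and unfolded protein genes, -0.07 for 18 integrated stress response genes and 0.02 for 17 p53 targets. For 19 hypoxia genes it was 0.03, for 24 antioxidant genes 0.01, for 20 clock genes 0.00, for 21 immediate-early genes 0.02 and for 23 interferon and antigen presentation genes -0.06. Examples were Acadm at 2787 and 3056 CPM, Ndufa4 at 1680 and 1910 CPM, Vldlr at 888.8 and 809.0 CPM and Gclm at 32.6 and 26.0 CPM. Medians, means and camera directions differed in sign for the acid-base, potassium channel, heat shock, circadian, antioxidant, immediate-early, endothelial and fibroblast lists, all with a median within 0.04 of 0.

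Of 27 lists tested, the red cell list was the 1 called by camera (adjusted p = 0.00027 at a preset correlation of 0.01). Its 9 tested members had a median log2 fold change of -0.82, and 9 passed adjusted over the list alone while 0 passed over all genes. With an estimated correlation the call was lost (adjusted p = 0.99), as it was by fry (adjusted p = 0.99). One wild-type heart stood apart, since Hbb-bs reached 11287 CPM in W2 and 1528 to 4987 CPM in the other 11 hearts. Without W2 the median was -0.26, 0 of the 9 members had an unadjusted p under 0.05 and the camera adjusted p was 0.064. Several haemoglobin genes held identical counts in all libraries, so these members are not independent. Next came the adipocyte markers (7 genes, median -0.51, adjusted p = 0.26) and the atrial markers (9 genes, median 0.09, adjusted p = 0.26). Leaving out W3 or K11 brought the adipocyte list below 0.05 (adjusted p = 0.028 and 0.00072), and leaving out W5 brought the atrial list to 0.016, all at the preset correlation. With an estimated correlation and all 12 hearts, the lowest adjusted p of the 27 lists was 0.987. Endothelial, fibroblast, smooth muscle, macrophage and mesothelial or nerve markers were not called. The lymphocyte and neutrophil list and the list for other tissues had 1 and 2 tested members, too few for a test.

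**Figure D2:**
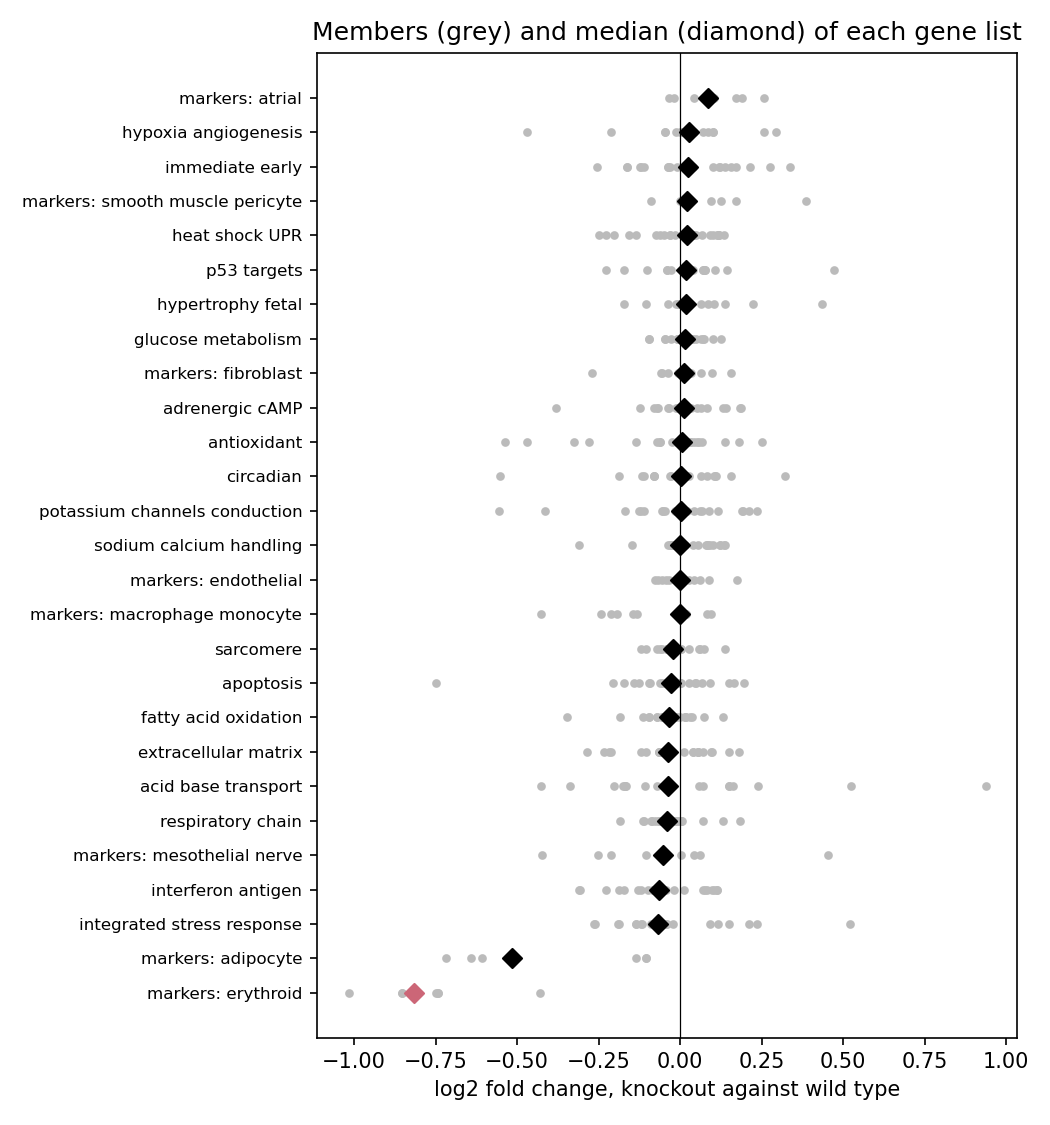
Log2 fold change of every tested member (grey points) and the median (diamonds) of 27 gene lists, knockout against wild type (horizontal axis). The red diamond marks the red cell list, with a median of -0.82, or -0.26 without W2. It was the 1 list called by camera at the preset correlation, and it was not called with an estimated correlation.

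**Figure D3:**
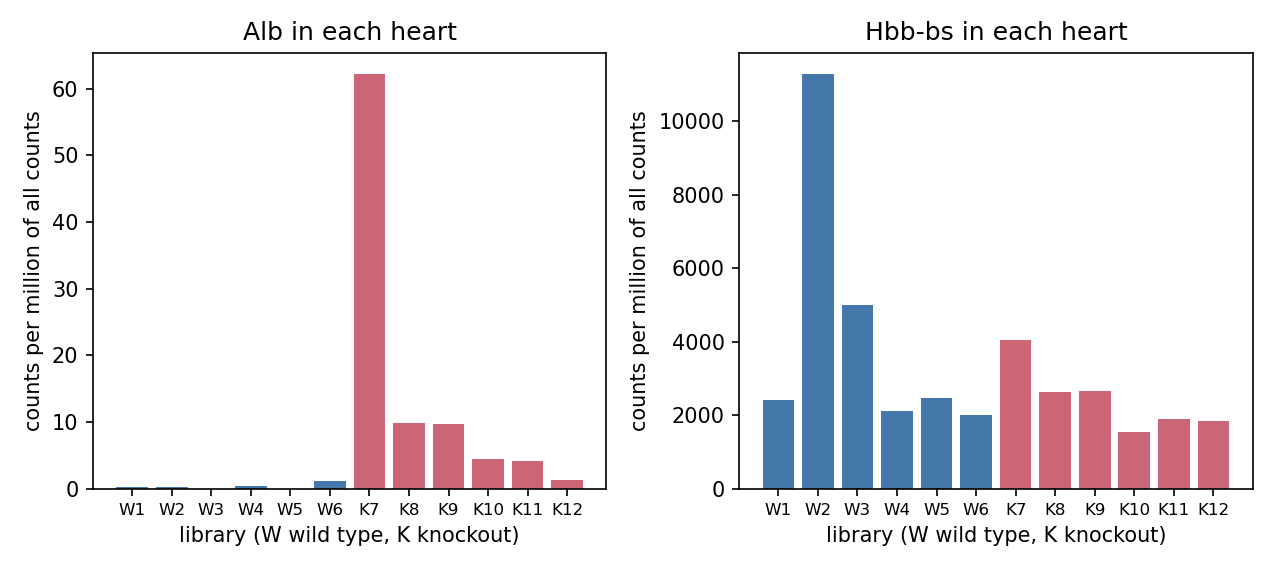
Alb (left) and Hbb-bs (right) in each heart, in CPM of all counts (vertical axes), for 6 wild-type and 6 knockout hearts (horizontal axes). Alb is highest in K7, at 62.2, and Hbb-bs is highest in W2, at 11287.

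The precision of these comparisons is shown by their standard errors. For 10762 genes with a mean of at least 5 CPM the median standard error of the log2 fold change was 0.10. In simulated counts with the same libraries, 200 of 13832 genes were changed, each of these with a mean of at least 5 CPM. There edgeR recovered 72% of genes changed 1.5-fold and 96% of those changed 2-fold. With fewer genes changed the adjustment is stricter, so these shares do not carry over to a comparison that called none. Slc4a4, at 42.8% lower, missed the threshold in the real hearts (edgeR adjusted p = 0.089). Genes below 5 CPM, such as Slc16a3, were not among those changed in the simulation.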

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

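Of the tests in this part, those of liver genes away from chromosome 5, of liver genes low in the heart, of both chromosome 4 explanations, of the genotype for the red cell genes (2 tests) and of other splits of the hearts (3 tests) were chosen only after the result was seen. The second genotype test for the liver genes and for the red cell genes was added because the first set a bound that single overlapping hearts meet, and the test of K7 alone because K7 carries most of the liver reads. After the first results were seen, the reading of 5 tests was also changed to leave their questions open. The first readings of both original genotype tests, of the liver genes low in the heart, of those away from chromosome 5 and of the chromosome 4 segment went against those explanations.

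Liver transcripts appeared in knockout libraries, most of all in K7, with Alb at 62.8 TMM-scaled CPM against 9.84 in the next knockout heart. Of 39 liver genes with at least 10 reads that had not been looked at before, 61.5% were highest in K7, where 8.33% would be expected by chance, which is consistent with liver RNA in the preparation or sequencing of some libraries. An effect on genes near Slc4a4 alone is argued against in K7 by 36 unseen liver genes on other chromosomes, whose median log2 ratio to wild type was 2.997, but it stays open in the other knockout hearts, where that median was 0.68 with 12 of 36 ratios negative (2.41 over all knockout hearts and 48 genes, 12 of them chosen for being high). An effect of the genotype stays open. In the sum of the unseen liver genes 5 knockout libraries lay within the wild-type range. But genes with a mean of at least 1 CPM over all 12 hearts made up 93.7% of the wild-type sum and would hide a small rise. Not all of these are expressed in wild-type hearts. Cyp3a11, at 8.47 CPM in K7 and at most 0.35 CPM in wild type, was among them, so the lower genes leave it out. In the unseen genes with a mean under 1 CPM, 3 knockout libraries lay within the wild-type range, while the liver genes seen first were higher in every knockout heart (4.10 CPM or more) than in every wild-type heart (2.34 CPM or less), and were chosen for that pattern.

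Red cell genes were lower in knockout by camera at the preset correlation, but not with an estimated correlation (camera adjusted p = 0.99). W2 held 2.45 to 4.70 times the median of the other hearts across the 9 members. More blood left in W2 alone is a possible explanation. Without W2 the camera adjusted p was 0.064 at the preset correlation of 0.01 (0.95 with an estimated correlation). In that run 0 of the 9 members had an unadjusted p under 0.05. Leaving out the highest heart of the higher group lowers its mean whatever the cause, so this does not decide the question. W3 had the next highest list score (9.61). Without both W2 and K7 the camera adjusted p was 0.00035 (0.92 with an estimated correlation). That decides nothing either, because K7 had the highest list score of the knockout hearts (9.18) and leaving it out lowers their mean. The genotype stays open, and 4 wild-type libraries lay at or under the highest knockout library in the list score, which a lower mean does not exclude. Without W2 the score differed by -0.26 (exact two-sided permutation p = 0.36).

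Zfp985, Lzic and Kif1b lie on chromosome 4 between 147553277 and 149503516 and had log2 fold changes of 1.10, 0.53 and 0.19, with edgeR adjusted p of 0.089, 0.88 and 0.999, so none passed the test; 6, 4 and 6 of 6 knockout hearts lay above every wild-type heart. The 7 other tested zinc finger genes within 1 Mb, picked by name, had a median log2 fold change of 0.082 (range -0.08 to 0.42) against 1.10 for Zfp985. This argues against reads shared between Zfp985 and those genes as a set, but how near-identical they are to Zfp985 was not checked. Copies with other names, copies farther away and copies too low to test were not covered, nor were Lzic and Kif1b. A linked chromosomal segment that differs between the groups may contribute and stays open, and Tmem51os1, at 142084298 and just outside the 5 Mb examined, was called by DESeq2 (0.067 CPM in wild type, 0.997 CPM in knockout, adjusted p = 0.0072). Of 84 other tested genes within 5 Mb, 3 had an unadjusted p under 0.05, 3.57% against 4.04% elsewhere (one-sided Fisher exact p = 0.67), and the exact 95% interval of that share, 0.74% to 10.1%, is too wide to exclude it. The genotype itself was not tested separately for these genes.

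Of the 462 possible splits of the hearts, 100 were used, the real grouping among them and the others drawn at random. For the count of 0 genes called they decide nothing, since all 100 must give at least 0, and the highest of the other splits gave 225. Chance could not be excluded for the genes at an unadjusted p under 0.05. There 58 of 100 splits, the real grouping included, gave at least 562 genes, and the other splits had a median of 599 and up to 2128. Nor could it be excluded for gene lists, where 85 of 100 splits, the real grouping included, gave at least the 1 list called. The other splits called a median of 3 lists and up to 9. Splits with several times the real count may point to a structure among the hearts, which was not tested.

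In groups of 6 hearts, 13 of 214 sets of values had 1 heart far from the others, where chance gives about 10.7. Besides Alb in K7, these were Mylk3 in K7 (715.6 CPM), Cry2 in W2 (53.3 CPM), Pi16 in W6 (64.2 CPM), Myh4 in W3 (13.9 CPM) and Slc8a1 in W2 (932.1 CPM). Nppb stood apart in W5 (143.3 CPM) and in K9 (217.1 CPM). In K11 the fat genes Pck1 (4.93 CPM) and Cidec (3.67 CPM) and the adipocyte list score (2.40) were high. The antioxidant list score was 6.15 in K9, and K7 was the deepest knockout library, at 12756955 counts. Among genes too low for the test, the summed CPM of Mup, Cyp3a41 and other liver genes was 62.5 in K7, 16.0 in the next library and at most 1.43 in wild type.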

How the results depend on the processing

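The edgeR exact test, 2 other quasi-likelihood options, shared counts taken once and the removal of W2 and K7 together were chosen after seeing the data. No paired analysis was made, because the labels name no pairs of hearts. A pairing that was not recorded cannot be excluded. The count of 0 genes held in 19 of the 30 alternatives. Among these, an adjusted p under 0.01, and one under 0.05 with a log2 fold change of at least 0.5, could only give 0. At an unadjusted p under 0.05 the main test had 562 genes, and the alternatives ran from 454 (without K12) to 985 (no low-count filter). DESeq2 gave 11 genes (9 higher, 2 lower), no low-count filter 16 (15 higher, 1 lower), 1 surrogate variable 2 (both higher), an adjusted p under 0.1 gave 3 (2 higher, 1 lower), and the edgeR exact test 5 (4 higher, 1 lower). Testing without the filter adds low genes, and 10 Mup genes were among those 16; for the others the cause was not tested. Leaving out 1 heart gave 0 to 2 genes, 0 to 2 higher and 0 to 1 lower, namely Lnpep without W6, Alb without K7, Slc4a4 without K8, Cacna1s without K9, Alb and an unnamed gene without K11, and Alb and Mup2 without K12. Other thresholds could not change the Slc4a4 log2 fold change, which kept its direction in the 30 alternatives, from -0.92 to -0.74. It passed the threshold in 5 of them, with -0.81 in DESeq2, -0.81 without the filter, -0.81 at an adjusted p under 0.1, -0.81 in the edgeR exact test and -0.92 without K8, and leaving out 1 heart gave -0.92 to -0.74. Its adjusted p ran from 0.00025 to 0.73. The 1 list called became 0 with an estimated correlation and with fry, and 0 to 2 with 1 heart left out, 0 of them without W2. Of 79 named genes, 4 (Myh7, Atp2a2, Pi16 and Nppb) changed sign in at least 1 setting, none of them called. The scalings moved the median of all genes by at most 0.01 on the log2 scale. With all hearts in, genes with few reads at this depth, such as Mup13 and Cyp3a41a, were left out of the edgeR test by the low-count filter.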

Other observations

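Genes of a cluster on chromosome 14 were lower in knockout hearts, as values that did not pass the test. Plac9a, Plac9b, Tmem254a, Tmem254b and Tmem254c lie between 25888403 and 26207025, with log2 fold changes of -0.90, -0.70, -0.59, -0.62 and -0.62. These are copies of Plac9 and copies of Tmem254, and Tmem254b and Tmem254c hold the same counts, so the values are not independent. Plac9a was highest in W3 (15.1 CPM), W4 (11.1 CPM) and W6 (11.4 CPM), and lay between 4.25 and 7.06 CPM in the other 9 hearts. The cluster was chosen after its values were seen, and no explanation was tested.

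One identifier that matched no gene name held 2.29% to 4.23% of all counts in each library. It averaged 3.16% in wild type and 3.14% in knockout (exact two-sided permutation p = 0.93). Another identifier without a name held 0 to 20 reads in wild-type libraries and 3 to 555 in knockout libraries, with the most in K7.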
